A study of Mus musculus with 6 samples.

How the data were processed

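RNA sequencing was done on 6 mouse samples in 3 groups: the As4.1 cell line, YFP-positive cells of Ren1c-YFP mice, and YFP-positive cells of Ren1c-/-; Ren1cYFP mice (4 libraries). Per the labels' protocols, native renin cells were freed from the kidney cortex of adult mice by enzyme digestion and sorted by fluorescence, and their libraries followed a manual of the Fluidigm C1 system. Values of the 4 Ren1c-/-; Ren1cYFP libraries were used, each column being tied to its sample by the labels. The samples of the other groups were not analysed here, so no test compares genotypes or cell types of different origin.

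The authors deposited TPM values (transcript abundance scaled to the same total in every library), with 2 decimals, for 32533 rows in each library, and every column sums to 1000000 within rounding. The submitters' processing notes name TopHat, Cufflinks and FastQC, without roles or versions, and the builds mm10 and GRCm38. Which tool gave the TPM values, the annotation, read filters, strand handling and the treatment of reads shared by paralogs are not given in the sources used here. TPM divides by transcript length and by each library's own total, so a rise in a few abundant transcripts lowers all others, and it keeps no read number. Depth is therefore unknown, and no counting interval or detection floor is given. An exact 0 is reported as listed at 0.

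Row names were matched to a mouse reference table of gene names, and 23918 of 32533 (73.5%) had a current or older symbol. Another 8381 rows carry sequence accessions as names, of which 191 matched, and these are not named in the text. They held 13.5, 12.9, 16.9 and 37.2% of TPM in replicates 1 to 4, and a pair among the 15 highest holds equal values in 3 libraries. Names turned into dates by a spreadsheet were on 27 rows. No row has the mt- prefix. Of 407 genes in the fixed lists, 402 had a row. The 5 without one were Ren1, Trbc2, Hba-a1, Hbb-b1 and Hbb-bt, which were not analysed here. Coordinates are those of the GENCODE annotation of GRCm38, counted from 1, and were given for genes whose symbol matched.

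Values were analysed as log2(TPM + 1), so a difference of low genes is understated. Before the data were examined, 23 gene lists were fixed (11 cell types, 6 pathways, 6 states), with 11 gene families, the tests and the rule for named genes. The rule took Ren1, up to 3 members of each list with the highest mean TPM, every renin cell identity member with a mean of at least 1 TPM, the 15 highest rows that are neither mitochondrial nor ribosomal protein genes, the 2 highest members of each family, and the 10 rows with the largest range among those with a mean of at least 50 TPM. YFP, Ren2, the identity members below 1 TPM and the genes high in every library were named after their values were seen.

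A list value is the mean over its members per library, given as mean ± SD over 4 libraries. The identity list was set against each of 10 other cell type lists, and the first member of a family against the second, with an exact sign-flip permutation test (16 sign patterns, two-sided, smallest p 0.13) and Benjamini-Hochberg adjustment. List level was placed among 10000 random lists of the same size, drawn from all rows, expressed or not. The range of a list over libraries was placed among 10000 random lists matched on mean expression in 20 bins, with adjustment over 23 lists. That permutation p describes these libraries against other genes and is not a test over animals. Agreement is Spearman's rho across rows for 6 library pairs. Outlying libraries were found with Dixon's ratio of gap to range, on log2 values for genes and lists against its 95% critical value for 4 values.

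Alternatives were a pseudocount of 0.1, quantile normalization, rescaling without the 84 ribosomal protein rows, the median over members, members with a mean of at least 1 TPM alone, other detection limits, and leaving out each library in turn. Setting values under 2% of a gene's highest library to 0, and detection at 20 TPM, were chosen after seeing the data. The list range test was checked on simulated data in 20 simulations of 32533 genes. A shift of 2 log2 units in 1 library, planted in the 20 proximal tubule members, was found in 75% of them, and 5.45% of unchanged lists were called at an unadjusted 0.05. Genes and libraries were drawn independently, with each gene's real mean and SD. Both rates therefore leave out genes that move together and libraries that differ as a whole. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.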

Results

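Transcript levels were measured by RNA sequencing in renin cells of the mouse, the cells of the kidney's afferent arterioles that make and release renin. The series covers 6 samples in 3 groups. One is As4.1, a tumoral mouse cell line that expresses renin. Another is native renin cells from reporter mice in which the Ren1c promoter drives yellow fluorescent protein (YFP). The remaining group is YFP-positive cells sorted from the kidney cortex of reporter mice that lack the renin gene (Ren1c-/-; Ren1cYFP), with 4 libraries, numbered here as replicates 1 to 4. The other two samples were not analysed here, so no genotype or cell line was compared, and every comparison below is between genes or gene lists within the 4 Ren1c-/-; Ren1cYFP libraries. Values were TPM (transcript abundance scaled to the same total in every library) as the authors deposited them. TPM keeps no sequencing depth, so the depth of each library is unknown. Nothing in the labels says that each library came from its own animal, so the spread between libraries may be technical.

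The reporter transcript was abundant in every library. YFP stood at 1179, 3163, 3007 and 1423 TPM in replicates 1 to 4, a mean of 2193 ± 1037 TPM (SD, n = 4). The targeted gene, Ren1, lies on chromosome 1 from 133350510 to 133360325 on the plus strand (GRCm38). Its own transcript was not analysed here, so the knockout was not checked from the targeted gene. Ren2, a near-identical paralog of Ren1, was listed at 0 in all 4 libraries. No single position in the GRCm38 annotation matched its name, so that 0 is not evidence that such a gene was silent. How reads shared by the 2 genes were assigned is unknown. The YFP and Ren2 values were added after the data were seen.

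The first question was which genes of the renin cell were expressed in cells that carry the active reporter but no renin gene. Crip1, a LIM-domain protein, stood at 12397 ± 3332 TPM (SD, n = 4). Akr1b7, an aldo-keto reductase used as a renin cell marker, stood at 4098 ± 1554 TPM, and Rgs5, a regulator of G protein signalling found in pericytes and vascular smooth muscle, at 2663 ± 1417 TPM. The connexin gene Gja4 had a mean of 415 ± 281 TPM and the nuclear receptor gene Nr2f2 a mean of 58.8 ± 25.7 TPM. These 5 genes were at 20 TPM or more in all 4 libraries. They lie on chromosome 12 from 113146316 to 113153879 (Crip1), chromosome 6 from 34412334 to 34423142 (Akr1b7), chromosome 1 from 169655501 to 169695813 (Rgs5), chromosome 4 from 127311421 to 127314039 (Gja4) and chromosome 7 from 70351944 to 70366735 (Nr2f2).

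Of the 19 measured members of the renin cell identity list, 15 had a mean of at least 1 TPM. Several owed that mean to few libraries. Mcam, a cell adhesion molecule of pericytes, was at 957 TPM in replicate 2 and between 9.25 and 58.2 TPM in the others. Cspg4, a pericyte proteoglycan, was at 546 TPM in replicate 1 and at most 14.2 TPM elsewhere. Gucy1a3, a subunit of soluble guanylate cyclase, lay between 54.5 and 70.2 TPM in 3 libraries and at 1.22 TPM in replicate 2. Its partner subunit Gucy1b3 reached 28.2 TPM in replicate 1 and at most 2.67 TPM in the others. Itga8 reached 42.3 TPM in replicate 4 and Pde3a, a cAMP-degrading phosphodiesterase, 29.6 TPM in replicate 3. Pdgfrb averaged 9.06 ± 6.64 TPM. Abcc9 lay between 0.13 and 9.04 TPM, Gja5 between 0.09 and 5.54 TPM and Kcnj8 between 0.24 and 3.78 TPM. The highest library of Adcy5 held 1.18 TPM, that of Adrb1 1.08 TPM and that of Ptger4 0.02 TPM, and Ptger2 was listed at 0 in all 4.

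**Figure D1:**
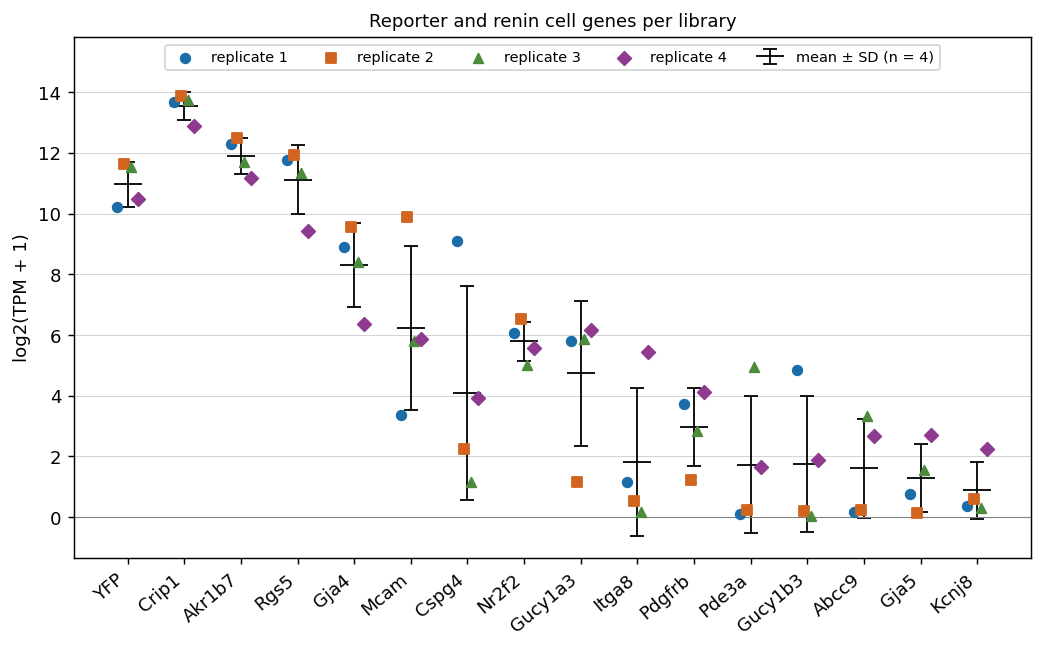
Reporter and renin cell identity genes on the log2(TPM + 1) scale, with 1 point per library and the mean ± SD over 4 libraries. Crip1, Akr1b7 and Rgs5 lie high in every library, while Cspg4 spans 7.95 and Mcam 6.55 log2 units.

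Markers of other cells of the kidney cortex were then set against the renin cell list, because the sort was on a renin reporter. Contractile genes of smooth muscle had the highest list mean of log2(TPM + 1) of the 11 cell type lists, averaged over the 4 libraries. In replicate 4 the erythroid list was higher, at 6.80 against 6.62. Tagln (transgelin) averaged 7056 ± 4736 TPM, Myl9 (a regulatory myosin light chain) 5938 ± 3157 TPM and Acta2 (smooth muscle actin) 4627 ± 2211 TPM (SD, n = 4). All 20 contractile genes had a mean of at least 1 TPM, and 9 were at 20 TPM or more in all 4 libraries. The list mean of log2(TPM + 1) was 6.62 ± 0.28 for contractile genes and 4.13 ± 0.32 for renin cell identity. The identity list was lower by a difference of -2.50 ± 0.18, in 4 of 4 libraries. Such differences, here and below, depend on which genes each list holds, and the identity list lacks a value for Ren1. They do not measure how much of each cell type was present.

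Stromal and mesangial genes had a list mean of 3.21 ± 0.24, with 4 of 19 members at 20 TPM or more in every library. Another 12 reached 20 TPM in no library, among them Lum (at most 15.2 TPM) and Pdgfra (at most 0.95 TPM). Vimentin (Vim) averaged 479 ± 273 TPM and the protease inhibitor Serpine2 419 ± 213 TPM. Complement factor H (Cfh) lay at 1236 and 919 TPM in replicates 2 and 3 and at 28.7 and 33.8 TPM in the others. The identity list exceeded the stromal list by 0.92 ± 0.51, in 4 of 4 libraries.

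Endothelial transcripts were the scarcest. The list mean was 0.19 ± 0.28, and 15 of 16 endothelial genes reached 20 TPM in no library. Esam was the exception at 88.9 TPM in replicate 4, against at most 0.56 TPM elsewhere. Ehd3 reached at most 0.45 TPM, and Vwf was listed at 0 in 3 libraries. The identity list exceeded the endothelial list by 3.94 ± 0.30, in 4 of 4 libraries.

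Podocyte genes had a list mean of 1.31 ± 0.48, from Synpo at 161 TPM in replicate 3, Nphs2 (podocin) at 129 TPM in replicate 1 and Mafb at 64.6 TPM in replicate 2. Myeloid genes had a list mean of 1.26 ± 0.32. Lyz2 (lysozyme) lay between 18.2 and 56.4 TPM in 3 libraries and at 116 TPM in replicate 2, Tyrobp averaged 13.5 ± 7.68 TPM and Fcer1g 9.82 ± 7.21 TPM, and 15 of 17 myeloid genes reached 20 TPM in no library. Lymphocyte genes had a list mean of 0.84 ± 0.66, from the T cell receptor component Cd3g at 544 TPM in replicate 3 and the cytotoxic cell genes Gzma and Nkg7 at 174 and 108 TPM in replicate 4. The identity list exceeded these lists by 2.82 ± 0.46 (podocyte), 2.86 ± 0.55 (myeloid) and 3.29 ± 0.63 (lymphocyte), in 4 of 4 libraries each.

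Tubule and red cell genes differed between libraries. Their list means were 3.26 ± 2.16 (proximal tubule), 1.38 ± 0.79 (loop of Henle), 1.84 ± 1.53 (distal tubule and collecting duct) and 3.27 ± 2.37 (erythroid). In replicate 4 the proximal tubule list mean was 6.35 and the erythroid list mean 6.80, both above the identity list of that library at 4.38. Hba-a2, an alpha globin gene, was at 21179 TPM in replicate 4 and at most 138 TPM elsewhere, and Hbb-bs, a beta globin gene, at 15022 TPM against at most 79.7 TPM. Aqp2, the water channel of collecting duct cells, was at 601 TPM there against at most 3.63 TPM, and Fxyd4 at 2395 TPM against at most 13.6 TPM. Replicate 1 also held tubule transcripts, with Miox at 988 TPM, Klk1 (tissue kallikrein) at 1079 TPM and Gpx3 (plasma glutathione peroxidase) at 2401 TPM. Aldob was highest in replicate 3, at 2046 TPM. In the loop of Henle list, Wfdc15b reached 317 TPM in replicate 1, Ppp1r1a 197 TPM in replicate 3 and Umod (uromodulin) 30.6 TPM in replicate 4. The identity list exceeded the loop of Henle list by 2.75 ± 0.66 and the distal tubule and collecting duct list by 2.29 ± 1.33, in 4 of 4 libraries each. Against the proximal tubule list it was higher by 0.87 ± 1.93, in 3 of 4 libraries, and against the erythroid list by 0.86 ± 2.24, in 3 of 4. Both of those differences were smaller than the spread between libraries.

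With 4 libraries, the exact sign-flip permutation test (two-sided) cannot give a p below 0.13, which is 2 of 16 sign patterns. The 8 differences with the same sign in every library had that value, and 0.156 after Benjamini-Hochberg adjustment over 10 lists. The exact permutation p was 0.375 (adjusted 0.417) for proximal tubule and 0.625 (adjusted 0.625) for erythroid genes. Without replicate 4, the identity list exceeded the proximal tubule list by 1.81 ± 0.50 and the erythroid list by 1.95 ± 0.60 (SD, n = 3), while the proximal tubule difference was 0.44 without replicate 2 and 0.47 without replicate 3, and the erythroid difference 0.37 without replicate 1 and 0.39 without replicate 3. With the median over members in place of the mean, the difference was -4.17 against contractile genes and 0.16 against stromal genes, and with members of mean TPM 1 or more alone it was -1.43 against contractile genes. The 4 of 4 sign was lost for stromal genes with a pseudocount of 0.1, under quantile normalization and with members of mean TPM 1 or more alone (exact permutation p = 0.25 each) and with the median (0.875), for distal tubule and collecting duct genes in the latter 3 settings (0.25, 0.25 and 0.375), and for endothelial genes with members of mean TPM 1 or more alone (0.25).

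**Figure D2:**
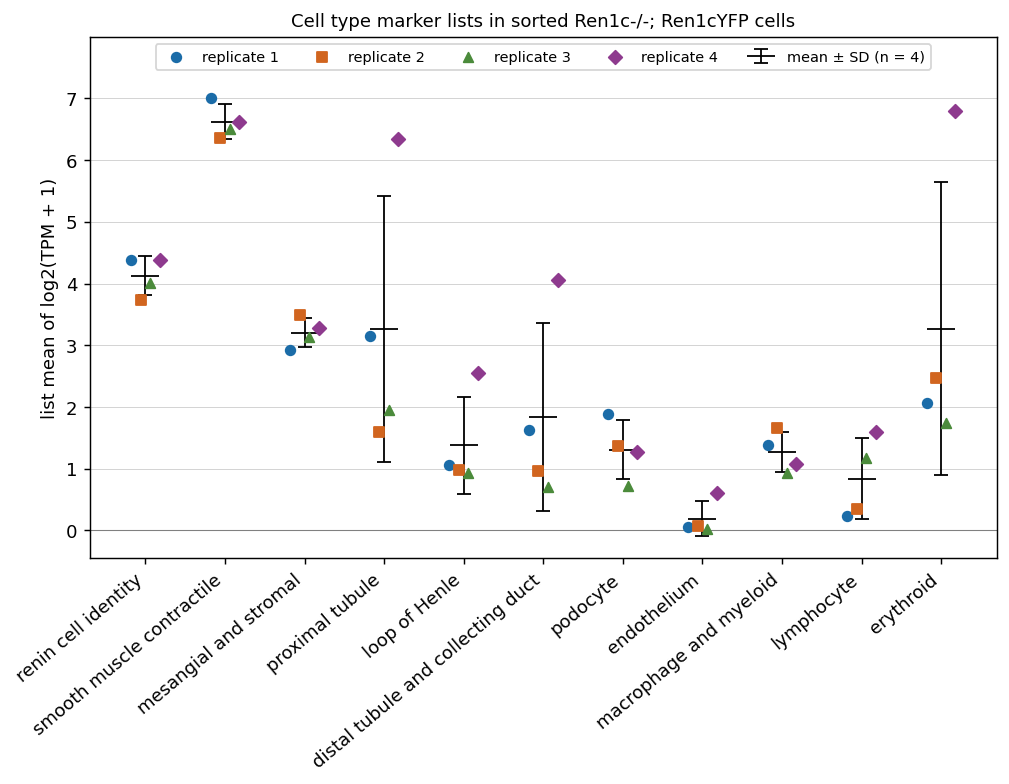
Mean log2(TPM + 1) over the members of each cell type list, with 1 point per library and the mean ± SD over 4 libraries. Contractile genes lie between 6.35 and 7.01 in every library, and replicate 4 stands above the others for proximal tubule (6.35), distal tubule and collecting duct (4.06) and erythroid genes (6.80).

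Signalling and regulatory genes were examined as 6 lists. Among cAMP pathway genes, 18 of 22 had a mean of at least 1 TPM, but only 6 reached 1 TPM in every library. Several, such as Adcy9 (20.9 TPM) and Ep300 (18.1 TPM), reached 1 TPM in replicate 4 alone. Gnas, the stimulatory G protein alpha subunit, was at 2560.5 TPM in replicate 1 and between 63.0 and 912 TPM in the others. Prkar1a, a regulatory subunit of protein kinase A, was at 549 TPM in replicate 3 and between 10.2 and 167 TPM in the others. The kinase inhibitor Pkig was at 581 TPM in replicate 3, 210.1 TPM in replicate 1 and at most 26.5 TPM in the others. Only Gnas was at 20 TPM or more in all 4 libraries. In the Notch list, the ligand gene Jag1 was steady at 457 ± 202 TPM (SD, n = 4) and was the only one of 17 members at 20 TPM or more in all 4. The receptor gene Notch2 was at 133 TPM in replicate 3 and between 10.1 and 46.3 TPM in the others, and the coactivator gene Maml2 at 124 TPM in replicate 3 and between 0.50 and 19.3 TPM in the others.

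Most transcription factor and coactivator genes reached 20 TPM in no library. Of 37 lineage transcription factors, 1 was at 20 TPM or more in all 4 libraries, 16 in some and 20 in none. Mef2c was at 314 and 400 TPM in replicates 1 and 2 and at most 12.04 TPM in the others. Meis1 was at 622 TPM in replicate 2 alone, and Epas1 at 252 and 191 TPM in replicates 1 and 4. Of 24 enhancer coactivators, 10 were at 20 TPM or more in some libraries and 14 in none. Med1, a Mediator subunit, reached 407 TPM in replicate 3 and at most 3.41 TPM elsewhere. The coactivator Ncoa3 averaged 81.8 ± 68.3 TPM. The chromatin remodeller Smarca4 was at 159.8 and 103 TPM in replicates 1 and 2 and at most 4.73 TPM in the others.

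In the renin-angiotensin list, cathepsin B (Ctsb) lay between 165 and 1338 TPM and was the single member at 20 TPM or more in all 4 libraries. Atp6ap2, the prorenin receptor gene, reached 194 TPM and the angiotensin receptor gene Agtr1a 121 TPM, both in replicate 2. Among lysosome and granule genes, Cd63 averaged 1962 ± 1506 TPM and Ctsz 449 ± 403 TPM. Ctsd (cathepsin D) was at 1021 TPM in replicate 3 and between 21.8 and 182 TPM in the others.

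Of the state lists, immediate early genes, which are induced within minutes of stimulation, came next to housekeeping genes. Fos averaged 2143 ± 1745 TPM and Egr1 819 ± 473 TPM. Btg2 was at 2804 and 1236 TPM in replicates 1 and 3 and at 147 and 121 TPM in replicates 2 and 4, and 7 of 20 members were at 20 TPM or more in all 4 libraries. Among stress genes, the chaperone Hspa8 averaged 2616 ± 1349 TPM and metallothionein Mt1 1691 ± 1352 TPM. Hspb1 was at 2096 TPM in replicate 2 and between 423 and 933 TPM in the others. Proliferation genes were low, with 12 of 14 reaching 20 TPM in no library. Pcna was at 147 TPM in replicate 4, Tyms at 40.3 TPM in replicate 3, and Mcm2 at 3.63 TPM at most. Of the hypoxia genes, Ldha was steady at 214 ± 70.8 TPM, while Ndrg1 reached 1039 TPM in replicate 2 and Bnip3 492 TPM in replicate 1. Of 16 interferon and inflammation genes, 12 reached 20 TPM in no library. The members with the highest means were high in single libraries, with Stat1 at 557 TPM and Il6 at 244 TPM in replicate 3 and Nfkbia at 1021 TPM in replicate 1. Housekeeping genes averaged 7791 ± 2132 TPM for Actb and 5582 ± 2074 TPM for Ppia, and Ubc lay between 485 and 9630 TPM.

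List means of log2(TPM + 1) were 2.65 ± 0.45 for the cAMP pathway, 1.95 ± 0.51 for Notch, 2.12 ± 0.57 for coactivators, 2.06 ± 0.69 for lineage transcription factors, 1.53 ± 0.48 for renin-angiotensin genes and 3.17 ± 0.74 for lysosome and granule genes (SD, n = 4). They were 5.53 ± 1.27 for immediate early, 5.01 ± 0.55 for stress, 0.77 ± 0.29 for proliferation, 2.51 ± 0.52 for hypoxia, 1.30 ± 0.35 for interferon and inflammation and 7.89 ± 0.56 for housekeeping genes. As a description, 9 of these 12 lists lay above the middle 95% of 10000 random lists of the same size. The exceptions were renin-angiotensin genes (percentile 95.5), interferon and inflammation genes (90.7) and proliferation genes (59.1). The random lists were drawn from all 32533 rows, of which 22412 were under 1 TPM in every library. A place above them therefore does not mark a list as high among expressed genes.

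**Figure D3:**
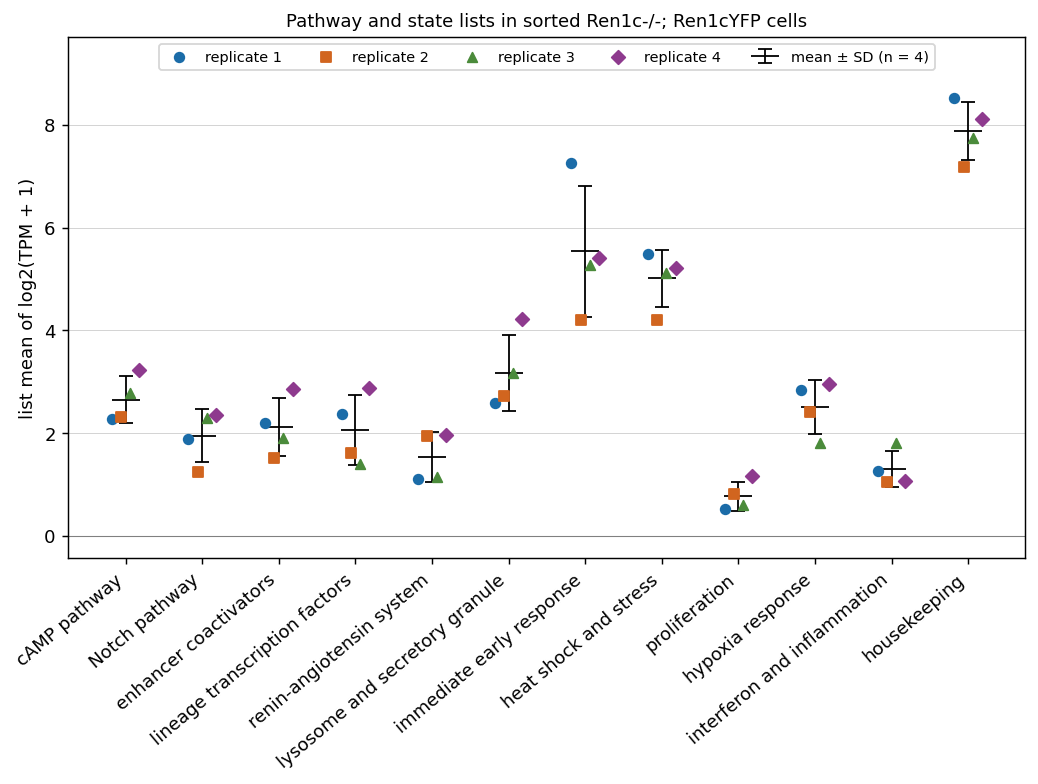
Mean log2(TPM + 1) over the members of each pathway or state list, with 1 point per library and the mean ± SD over 4 libraries. Immediate early genes range from 4.20 in replicate 2 to 7.26 in replicate 1, and proliferation genes lie between 0.52 and 1.16.

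The list means of 5 of 23 lists differed more between libraries than those of matched random lists. The range of the list mean over the 4 libraries was 5.06 log2 units for erythroid, 4.75 for proximal tubule and 3.36 for distal tubule and collecting duct genes, each highest in replicate 4. Each exceeded all 10000 random lists matched on mean expression (adjusted permutation p = 0.000767 over 23 lists, from the smallest p that 10000 draws can give). Immediate early genes ranged over 3.07 units, with 13 of 20 members highest in replicate 1 (adjusted permutation p = 0.0115). Housekeeping and stress genes were also highest in replicate 1 and lowest in replicate 2, over 1.33 and 1.27 units, neither beyond matched lists. Endothelial genes ranged over 0.58 units (adjusted permutation p = 0.0359) and were highest in replicate 4, where Esam was the single member at 20 TPM or more. That call was lost with a pseudocount of 0.1 (adjusted permutation p = 0.0635), under quantile normalization (0.330), with members of mean TPM 1 or more alone (0.609), with the median over members (0.955) and without replicate 1 (0.0696). The immediate early call was lost with the median over members (adjusted permutation p = 0.314). Renin cell identity ranged over 0.65 units, smooth muscle over 0.66 and stromal genes over 0.56, and for these and the other 15 lists the adjusted permutation p was 0.965. Without replicate 4, the ranges were 1.56 for proximal tubule, 0.94 for distal tubule and collecting duct, 0.05 for endothelial and 0.73 for erythroid genes, with adjusted permutation p from 0.448 to 0.845. The immediate early range was 1.21 without replicate 1 (adjusted permutation p = 0.980) and 2.00 without replicate 2 (0.358).

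Among gene families, the member with the highest mean TPM was higher than the second in 4 of 4 libraries for 5 of 11 families. The 2 members were ranked on these same libraries, so the direction of each difference was chosen from the data and its p is descriptive. Akr1b7 exceeded Akr1b3 by 5.51 ± 2.69 on the log2(TPM + 1) scale, Rgs5 exceeded Rgs2 by 4.73 ± 3.39, the transcription factor Nfia exceeded Nfib by 2.72 ± 1.40, Pdgfrb exceeded Pdgfra by 2.51 ± 1.59 and Notch2 exceeded Notch3 by 1.06 ± 0.46 (SD, n = 4). For these 5 the exact sign-flip permutation p was 0.13, the smallest possible, and 0.275 after adjustment over 11 families. In replicate 2, Pdgfrb led at only 1.35 against 0.95 TPM for Pdgfra. Gja4 led the connexins in 3 libraries, and Gjc1 was higher in replicate 4 at 119 TPM against 81.9 TPM for Gja4, a mean difference of 5.76 ± 4.20. Adcy6 exceeded the adenylyl cyclase Adcy9 in 3 of 4 libraries (2.02 ± 4.55), and Agtr1a exceeded Agtr2 in 3 of 4 (2.38 ± 2.34). In replicate 1, Adcy6 led at only 0.29 against 0.11 TPM. Among prostaglandin receptors, Ptgir reached 161 TPM in replicate 1 and Ptger1 74.6 TPM in replicate 4 (1.17 ± 4.03). Pde8b, at 174 TPM in replicate 1, and Pde4b, at 98.0 TPM in replicate 3, led the cAMP phosphodiesterases in different libraries (-1.52 ± 5.52). Adrb1 and Adrb2 stayed at or below 1.08 TPM (0.21 ± 0.53). For these 6 families the exact permutation p lay between 0.25 and 1 (adjusted 0.393 to 1).

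The most abundant gene outside the ribosomal proteins that carries a gene symbol was Mgp (matrix Gla protein, an inhibitor of vascular calcification), at 13177 ± 3393 TPM (SD, n = 4). Crip1 followed, then the myosin light chain Myl6 at 10016 ± 2804 TPM, ubiquitin Ubb at 8635 ± 5957 TPM, Actb, thymosin Tmsb4x at 7468 ± 2382 TPM, Tagln, and S100a11 at 6981 ± 3446 TPM. Another 7 of the 15 highest were listed under sequence accessions and are not named. The 10 highest rows held 16.5, 16.1, 17.9 and 36.5% of all TPM in replicates 1 to 4. Ribosomal protein genes held 12.7, 13.4, 12.4 and 9.19%.

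Replicate libraries differed widely below the most abundant genes. The number of the 32533 rows at 1 TPM or more was 4771, 4961, 3132 and 8485 in replicates 1 to 4, and 2184 rows reached it in all 4. Spearman's rho across all rows lay between 0.823 and 0.888 over the 6 pairs of libraries (median 0.858), and between 0.240 and 0.650 among rows with a mean of at least 1 TPM. Rows are not independent replicates, so no p is given. Of 3890 rows with a mean of at least 10 TPM, 3555 (91.4%) differed by at least 3 log2 units between their highest and lowest library. The largest ranges among genes with a mean of at least 50 TPM included Plgrkt at 3551 TPM, Qars at 3592 TPM, Nrbp1 at 1959 TPM, Rtfdc1 at 1539 TPM, Sirt5 at 1502 TPM and Eral1 at 1165 TPM in replicate 2, and Rab20 at 3061 TPM and the small nucleolar RNA Snora31 at 2737 TPM in replicate 1. In its lowest library, each of these 8 genes held at most 3.54 TPM.

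Genes high in one library alone (at least 200 TPM there and under 5% of that value in each other) were listed at low values in the others. The median of those low values was between 0.152 and 1.28% of the high library's value over the 12 ordered pairs of libraries. Low values in replicate 4 were widely spread. For genes high in replicate 2 alone, their quartiles were 0.113 and 2.36%, against 0.112 and 0.224% in replicate 3. Between replicates 2 and 3 the low values kept a ratio. Over genes high in replicate 4 alone, the median of log2(replicate 2 / replicate 3) was 1.80 (quartiles 1.46 and 2.07). The 6 myeloid markers with a mean of at least 1 TPM had a median of 2.02, and the 310 rows at 50 TPM or more in every library a median of -0.06.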

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

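The tests of explanations in this part were chosen after the result was seen. A library is given here when its gap to the nearest of the others, divided by the range of the 4, exceeds the 95% critical value of Dixon's test. This held for 3 of 23 lists, 2 of 4 library measures and 26 of 121 genes. Chance gives about 1 in 20 for normally distributed values. Most of these genes were named for a high mean, and many were nearly absent from some libraries. The count of 26 is therefore not read as an excess.

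Replicate 4 stood apart in 3 cell type lists, loop of Henle (gap over range 0.923), endothelium (0.918) and erythroid (0.856). The loop of Henle range of 1.63 log2 units was not beyond matched lists (adjusted permutation p = 0.965). It also stood apart in the share of TPM in the 10 highest rows (0.913, 36.5% against 16.1 to 17.9%) and in the share of TPM held by rows named by accession (0.835, 37.2% against 12.9 to 16.9%). Tubule and red cell genes high there included Fxyd4 (0.853), Aqp2 (0.880) and Hbb-bs (0.846). Of 38 detected tubule and erythroid markers, 31 (81.6%) had their highest value in replicate 4. That count restates the pattern, so it is no separate test of RNA of tubule and red cells as its source. The transcripts themselves were high there, with Hba-a2 at 21179 TPM and Aqp2 at 601 TPM. How they came into that library stays open. The share of 81.6% was above the middle 95% of lists matched on mean expression, which ended at 57.9%. The markers were taken from lists already seen to be high in replicate 4. This comparison therefore cannot settle whether more genes being detected in that library accounts for the pattern. A mislabelled library of other cells is argued against by YFP, Crip1, Akr1b7 and Rgs5, whose median in replicate 4 was 51.7% of their mean in the others. The sort was for YFP-positive cells, but its purity was not examined here, so it cannot exclude tubule and red cells. No biological explanation was tested because the libraries are of 1 group.

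Other genes flagged as high in replicate 4 were Esam (gap over range 0.924, 88.9 TPM), Gzma (0.921, 174 TPM), Nkg7 (0.907, 108 TPM), Adcy9 (0.961, 20.9 TPM), Gjc1 (0.875, 119 TPM) and Ptger1 (0.951, 74.6 TPM). Also flagged there, at values under 5 TPM, were Kcnj8 (0.854, 3.78 TPM), Vwf (1, 0.78 TPM) and Mcm2 (0.969, 3.63 TPM). Egr1 was lowest there (0.867, 144 TPM against 939 to 1252 TPM). In replicate 1 alone, Pde8b (0.912, 174 TPM), Adrb1 (0.973, 1.08 TPM) and Rab20 (0.832, 3061 TPM) were high. In replicate 2, Meis1 (0.877, 622 TPM), Plgrkt (0.869, 3551 TPM), Sirt5 (0.878, 1502 TPM), Eral1 (0.914, 1165 TPM) and Rtfdc1 (0.915, 1539 TPM) were high, while Gucy1a3 (0.928, 1.22 TPM) and Rgs2 (0.841, 3.93 TPM) were low. In replicate 3, Med1 (0.836, 407 TPM) and Il6 (0.883, 244 TPM) were high and Nfia (0.853, 22.1 TPM against 84.9 to 107 TPM) was low. Plgrkt, Rab20, Sirt5, Eral1 and Rtfdc1 were named for their large range, so their place here follows from that choice.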

How the results depend on the processing

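Setting values under 2% of a gene's highest library to 0 and detection at 20 TPM were tests chosen after seeing the data. Across 783 recomputed values, the 10 mean differences between renin cell identity and another cell type kept their sign in every setting run, leave-one-out included. The sign in each library did not for stromal, distal tubule and endothelial genes, where the exact permutation p reached 0.25 to 0.875, and 4 libraries cannot give a p under 0.13 and 3 cannot give one under 0.25. Rows detected in all 4 libraries numbered 2184 at 1 TPM, 7032 at 0.1 TPM, 869 at 5 TPM, 457 at 20 TPM and 1152 with values under 2% set to 0. Median agreement was 0.858, 0.439 among rows with a mean of at least 1 TPM, and 0.656 as Pearson's r of log2 values. Variable rows numbered 3555, and 1639 with a mean of at least 50 TPM, where fewer rows are tested. The 50 highest rows held 41.0% of TPM. Lists with a range beyond matched lists numbered 5, 4 with a pseudocount of 0.1 (without endothelial genes), 3 with the median over members, and 1 to 5 when a library was left out (1 without replicate 4, 3 without replicate 1). Families whose first member led in every library numbered 5, and 5 to 8 when a library was left out, with 8 without replicate 4. Among families without a call, the prostaglandin receptor difference ran from -0.75 (without replicate 1) to 2.40, the beta-adrenergic one from -0.0515 (without replicate 1) to 0.31 and the cAMP phosphodiesterase one from -4.01 to 0.0704 (without replicate 3). The adenylyl cyclase difference of 2.02 ran from 0.61 (without replicate 3; 0.96 without replicate 2) to 3.88 (without replicate 4), the angiotensin receptor one of 2.38 fell to 1.45 without replicate 2, and that of Rgs5 over Rgs2, 4.73, to 3.10 without replicate 2. The cause of these shifts was not tested. Of the other values of single lists and families, 567 stayed within 1 SD or on their side of the threshold, 12 list ranges lost their call, 1 gained one (interferon and inflammation under quantile normalization) and 45 list levels moved by more than 1 SD, under the pseudocount of 0.1, the median over members or the filter on low members. Ren1 has no value, so its alternatives were not run. No paired analysis was possible because a single group was analysed. Depth is unknown, so what it limits cannot be stated.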

Other observations

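Beyond the fixed lists, 310 rows were at 50 TPM or more in every library. They comprised 67 ribosomal protein rows, 20 rows named by accession, 35 members of fixed lists and 189 others, with Rplp0 both a ribosomal protein row and a list member. Of these others, 40 differed by less than 3 times between the highest and lowest library. The ferritin chains Ftl1 and Fth1 stood at 4487 ± 1086 and 2380 ± 344 TPM (SD, n = 4). Subunits of the respiratory chain included Cox4i1 at 2521 ± 800 TPM, Cox6c at 2061 ± 528 TPM and Uqcr11 at 1810 ± 506 TPM, and the ATP synthase subunit Atp5l stood at 1856 ± 251 TPM. The nuclear RNA Malat1 was at 1334 ± 269 TPM. High in every library but more spread were Igfbp7, a growth factor binding protein, from 914 to 3746 TPM, Rarres2 (chemerin) at 1935 ± 1456 TPM, the actin-binding protein gene Cald1 (caldesmon) at 2802 ± 1450 TPM and the transcriptional inhibitor Id3, from 640 to 8885 TPM. The carboxypeptidase E gene Cpe, an enzyme of prohormone processing, ranged from 203 to 7628 TPM, and Ifitm3 from 1130 to 10699 TPM. These genes were named after their values were seen, and no enrichment was tested.

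By fixed list, the 35 genes included 9 of the 20 contractile genes, 4 renin cell identity genes, 7 housekeeping genes, 4 immediate early genes, 4 stress genes and 2 stromal genes. Proximal tubule, loop of Henle, distal tubule, podocyte, endothelial, myeloid, lymphocyte and erythroid lists each had 0.

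Low values kept a similar median ratio between replicates 2 and 3, and the tests in this paragraph were chosen after the result was seen. Over genes high in replicate 4 alone, log2(replicate 2 / replicate 3) had a median of 1.80. A further 2139 genes were above 0 in every library, with their highest library between 1 and 5 TPM. Their median was 1.78 (quartiles 0.967 and 2.39). The difference of 0.0224 met the prediction for reads from a common source outside the 4 libraries, as a hypothesis. Keeping only genes above 0 in every library favours genes with such shared low values, so the test cannot settle it. The myeloid markers differed from the genes high in replicate 4 alone by 0.223, which went against the prediction for macrophages among the sorted cells. All 6 detected markers were highest in replicate 2, and macrophage RNA mainly in that library could give the same ratio. The source of the myeloid values, Lyz2 at 29.4 to 116 TPM in replicates 1 to 3 included, therefore stays open. Reads carried over between the 4 libraries stay open. Spearman's rho across genes between the value in replicate 4 and that in another library was 0.364 (median of 3), between the bounds of 0.7 for and 0.3 against carry-over. The same measure for genes high in replicate 1, 2 or 3 alone ran from 0.288 (replicate 3 to 4) to 0.762 (replicate 3 to 2), and it also passed 0.7 from replicate 3 to 1 (0.720) and from replicate 2 to 3 (0.718). The same 2139 genes, above 0 and under 5 TPM in every library, held in replicate 2 a median of 21.3% of their highest other library. The bootstrap interval of 19.7 to 23.0 includes the bound of 20%.

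Genes were often present in some libraries and nearly absent from others, and both tests of this pattern were fixed before the results were seen. A candidate explanation is that few RNA molecules were sampled per gene. The share of rows with a library under 5% of the highest was 91.5% at a mean of 50 to 200 TPM and 8.57% above 2000 TPM, a ratio of 10.7. Pathway differences between the libraries cannot be told apart from this, since 1 of the 12 pathway and state lists (immediate early genes) had a range above the middle 95% of matched lists, where 3 were required and 0 would have spoken against it. The number of cells behind each library is not given in the sources used here, and sampling was not measured directly.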
